A study of Mus musculus with 4 samples.

How the data were processed

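Liver cells of male wild-type C57BL/6 mice were profiled by droplet single-cell RNA sequencing after 6 weeks on control food (NCD) or on food that lacks methionine and choline (MCD), a diet which is widely used to produce fatty liver with inflammation in mice. The mice were 8 weeks old and matched for weight when they were obtained. Each diet has 2 libraries. Whether a library holds 1 mouse or a pool is not given in the sources used here. The sort took live (7AAD-negative) CD45+ Ly6G- cells with intermediate CD11b. The series text gives the F4/80 level of the sort as low and the sample labels give it as high, and the files do not settle which is right. Diet and preparation batch cannot be told apart, since no label gives a batch and each library belongs to 1 diet.

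The deposited values are UMI counts per gene and cell barcode, which the authors made with Cell Ranger against mm10 per the submitters' processing notes, from single cell 3' v3 libraries. Per the file headers the Cell Ranger version was 3.0.2. The settings of cell calling and any further filter on barcodes are not given in the sources used here. MCD replicate 1 was counted on 27998 genes and the other 3 libraries on 28692, and the 694 additional genes, mainly immunoglobulin and T cell receptor segments, took at most 0.119% of a library's UMIs. All analyses used the 27998 shared genes. Of these, 27722 matched the gene annotation used for positions, GC content and transcript length (GENCODE M21, GRCm38). The 65 symbols that stood on 2 gene identifiers were kept apart by identifier.

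Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, and doublets were called per library with Scrublet at an expected rate of 5%. The caller named 7 barcodes, 0.0728% of those that passed, so it has not worked here and doublets must be taken as still present. This left 9602 cells. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were selected by library, and 30 principal components and 15 neighbours per cell went into Leiden clustering at resolution 1.0, with no integration across libraries (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Clusters at resolution 2.0 with a median of more than 1% of UMIs from the hepatocyte list were set apart as hepatocyte-rich. Clusters were named from 24 lists of cell type markers. In each cluster and diet with at least 20 cells, genes were ranked by the ratio of summed CPM (UMIs scaled to a common library total, with 20 added) to the other cells of that diet, and the cluster took the name of the list with most members among the top 50 genes. At least 3 members there and 1 in the top 10 were needed, and no other list was allowed more members in the top 10. A cluster whose cells of the 2 diets got different names was left unnamed, except that among the 4 monocyte and macrophage names it took that of the diet with more cells. An eosinophil-like cluster of 48 MCD cells had 2 eosinophil and 2 neutrophil markers in its top 10. These naming rules and an exact integer form of the neighbour graph were settled after the clusters had been seen. The names are therefore labels by likeness of transcripts, not of surface proteins.

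The library was the unit of replication. UMIs were summed per library over the cells of a class, and diets were compared with the edgeR quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after TMM scaling and the filterByExpr filter by diet, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene given below comes from this test. The comparisons were the diet effect in the union of the 4 monocyte and macrophage classes, in each class with at least 20 cells in every library, and in all retained cells, and the class by diet term between the Ly6Chi-like and Ly6Clo-like monocytes with library as a block. Fold changes are MCD over NCD. For a gene with no UMI in a diet the fold is a lower bound against a floor of 3 counts over that diet's libraries. Means are given with the SD of 2 libraries and log2 fold changes with the standard error (SE) of the fit.

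A total of 24 gene lists and the 24 marker lists were tested with limma camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a family, and again with an estimated correlation and with fry. Camera compares a list with the other genes. Fry tests whether a list's genes move on balance in one direction. Marker lists with fewer than 3 measured members were not tested. Shares of cells were compared per library with exact Clopper-Pearson intervals of 95%, which cover counting error only, and 2 libraries against 2 allow no exact two-sided permutation p under 0.333. Shares of cells with a UMI of a marker gene were taken after thinning each cell to 1000 UMIs, and the upper limit given beside a share of 0 is 3 over the number of cells.

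The genes named in the text follow a rule. In the union of monocyte and macrophage classes they are the 8 largest rises and falls among genes that passed, with both MCD libraries on the same side of both NCD libraries and a mean of at least 50 CPM in the higher diet, without ribosomal protein genes, mitochondrial genes and clone or model names. In every other comparison the 4 largest rises and falls are taken by the same rule. Up to 4 members of each gene list with the smallest p and the 2 members with the highest mean CPM may be named, and so may the 2 most abundant members of each marker list. Ptprc, Itgam, Adgre1, Ly6g, Ly6c2, Ccr2, Cx3cr1, Trem2, Gpnmb, Spp1, Cd9, Clec4f, Timd4 and Mki67 are always named. Members named outside the rule are marked as chosen after their values were seen. The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

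Alternatives were DESeq2 1.42.0 in place of edgeR, size factors by the RLE method, scaling by library totals alone, no filter on low counts, counts thinned to the smallest library, each library left out in turn, a replicate block, stricter and looser cell filters, doublets kept, other clusterings, equal weight to each class and a correction of the trend of fold change over GC content. Scaling by library totals, the removal of the highest 5% of doublet scores, the inclusion of the unnamed clusters, clustering on values scaled within each library, the class without its lipid-associated cluster and the GC correction were added after the data had been seen. The edgeR test was checked on simulated counts with the depths of these libraries. In the monocyte and macrophage union it recovered 52% of simulated 2-fold and 88% of 4-fold changes and called 9 unchanged genes among 10815 tested. The simulation changed 100 genes at each fold, far fewer than passed in the real data, and held no GC trend. Of 10 simulated lists moved by 1.5-fold all 10 were called, and 1 of 10 unmoved lists was. These lists were random genes drawn independently of each other. The simulation therefore cannot show how camera with the preset value behaves when genes of a list are correlated. Clusters 9 and 14 were left unnamed and stand outside the classes, and the figures were drawn with matplotlib 3.10.9.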

Results

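Intrahepatic cells sorted as monocyte-derived macrophages were compared between mice on control food (NCD) and mice on food lacking methionine and choline (MCD), with 2 single-cell libraries per diet, to describe how this population differs in fatty liver disease. The 4 libraries held 12306 cell barcodes, 2783 and 2699 in NCD replicates 1 and 2 and 3349 and 3475 in MCD replicates 1 and 2. Total counts were 7518597 and 7428431 UMIs in the NCD libraries and 32975974 and 37772284 UMIs in the MCD libraries. After filtering, 1733 and 1784 NCD cells and 2948 and 3137 MCD cells remained. The median retained cell held 2170 and 2252.5 UMIs in the NCD libraries and 12043.5 and 12299 UMIs in the MCD libraries. More than 10% mitochondrial UMIs were found in 36.7% and 32.8% of NCD barcodes and in 8.06% and 7.22% of MCD barcodes. Ribosomal protein transcripts took 26.4% and 23.5% of NCD UMIs and 17.9% and 17.8% of MCD UMIs. Depth, mitochondrial share and ribosomal share thus separated the libraries by diet.

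The 9602 retained cells fell into 24 clusters, and most clusters held cells of 1 diet. Ly6Chi-like monocytes, which are classical inflammatory monocytes, were cluster 1 with 640 and 861 MCD cells and cluster 4 with 403 and 443 NCD cells. Ly6Clo-like monocytes, which patrol the vessel wall, were cluster 5 with 365 and 360 MCD cells and cluster 10 with 158 and 174 NCD cells. C1q-expressing macrophages formed cluster 11 with 46 and 64 MCD and 69 and 50 NCD cells. A cluster like lipid-associated macrophages, with Gpnmb, Spp1 and Lpl among its top genes, held 501 and 415 MCD cells and 1 and 3 NCD cells. No cluster was named Kupffer cell-like, but the NCD cells of cluster 11 had 3 macrophage and 3 Kupffer cell markers (Vsig4, Slc40a1, Cd5l) among their top 10 genes, a tie, while its MCD cells had 5 macrophage markers. The other named clusters were cDC2-like, migratory DC-like, endothelial, eosinophil-like, NK-like, neutrophil-like, basophil-like, B and T cells. Clusters 9 and 14, rich in the interferon-inducible Cxcl9 and Cxcl10, stayed unnamed. The NCD cells of cluster 9 also had Ccl24 in their top 10, as had the MCD cells of the lipid-associated macrophage-like cluster. Endothelial cells were thus present although the sort was set for CD45+ cells with intermediate CD11b, and eosinophil-like cells were present as well.

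In the union of the 4 monocyte and macrophage classes, Hp, Gdf15, Gadd45b and Ier3 were among the largest rises on MCD. Hp, which encodes the haemoglobin-binding protein haptoglobin, rose from 71.1 ± 11.8 to 705 ± 15.2 CPM (SD, n = 2 libraries per diet), a log2 fold change of 3.31 ± 0.13 (SE). Gdf15, a stress-induced cytokine, rose by 3.28 ± 0.24 on the log2 scale, the stress response gene Gadd45b by 3.17 ± 0.25, and the immediate early gene Ier3 by 2.92 ± 0.15. Lars2, the mitochondrial leucyl-tRNA synthetase, rose from 5.46 ± 2.31 to 77.8 ± 1.31 CPM. Among the falls, Cd300e, a receptor of mature monocytes, went from 100.2 ± 0.151 to 8.98 ± 0.0860 CPM, and Fabp4, a fatty acid-binding protein, from 181 ± 34.6 to 18.1 ± 6.90 CPM. Slc40a1, the iron exporter ferroportin, fell by 4.39 ± 0.48, the platelet and macrophage chemokine Pf4 fell by 4.03 ± 0.54, and the leukocyte receptor Lilra5 fell by 2.94 ± 0.22 on the log2 scale. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p of these genes ran from 2.59e-06 for Cd300e to 6.74e-04 for Pf4.

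Hp (ENSMUSG00000031722) lies on chromosome 8 from 109575128 to 109579172, Gdf15 (ENSMUSG00000038508) on chromosome 8 from 70629393 to 70632456, and Fabp4 (ENSMUSG00000062515) on chromosome 3 from 10204088 to 10208576 of GRCm38. Gpnmb (ENSMUSG00000029816) lies on chromosome 6 from 49036546 to 49070929, and Trem2 (ENSMUSG00000023992) and H2-Aa (ENSMUSG00000036594) on chromosome 17, from 48346401 to 48354147 and from 34282744 to 34287823. Each is annotated as a protein-coding gene.

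Several of the largest changes rest on 1 library, 1 cluster or a few cells. Spp1, which encodes osteopontin, rose by 3.05 ± 0.73 on the log2 scale and the tetraspanin Cd63 by 3.24 ± 0.52. Without the lipid-associated macrophage-like cluster these values were 0.61 (adjusted p = 0.299) and 0.76 (adjusted p = 0.0883). The call of Spp1 was also lost without NCD replicate 1 (adjusted p = 0.172) or 2 (0.147) and with up to 20% mitochondrial UMIs (0.0642), and that of Cd63 without NCD replicate 2 (0.0709). Erdr1 rose by 3.67 ± 0.84, with 192 and 51.6 CPM in the MCD libraries. It did not pass without NCD replicate 1 (adjusted p = 0.165) or 2 (0.11) or with the GC trend removed (0.0592), and its near-identical copies make its count uncertain. The immunoglobulin joining chain Jchain fell by 10.1 ± 1.62, but 473 of its 483 UMIs in NCD replicate 1 came from 1 cell. The neutrophil granule gene Camp fell by 9.63 ± 1.64, and 372 of its 675 UMIs in that library came from 1 cell. Without NCD replicate 1 the log2 value of Camp was -3.44 (adjusted p = 0.296). Retnla, a product of alternatively activated macrophages, fell by 5.41 ± 0.85 and was seen in 8 and 9 NCD cells. Its call was lost without NCD replicate 2 (adjusted p = 0.0569). All these adjusted p are from edgeR.

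Of the genes that define the sort and the lineage, the pan-leukocyte gene Ptprc (CD45) fell by 0.66 ± 0.09 on the log2 scale and Adgre1, which encodes F4/80, went from 178 ± 5.6 to 104 ± 3.86 CPM, a fall of 0.77 ± 0.10 with an adjusted p of 4.82e-04 in edgeR. Itgam, which encodes CD11b, did not pass (log2 fold change -0.23, adjusted p = 0.0822), nor did the monocyte genes Ccr2 (-0.24, 0.0772) and Ly6c2 (-0.01, 0.986). Scaled by library totals, the values of Itgam, Ccr2 and Ly6c2 were 0.11, 0.10 and 0.32, and none passed. Ccr2 passed when counts were thinned (-0.31), at Leiden resolution 0.5 (-0.31) and with the unnamed clusters included (-0.30), and Ly6c2 without MCD replicate 2 (-0.51). The fractalkine receptor Cx3cr1 went from 382 ± 18.9 to 183 ± 8.16 CPM, a fall of 1.06 ± 0.10. Trem2, a lipid-sensing receptor of macrophages, rose from 24.4 ± 3.39 to 94.6 ± 5.65 CPM, and the glycoprotein gene Gpnmb from 3.63 ± 1.89 to 42.7 ± 1.09 CPM, log2 rises of 1.96 ± 0.15 and 3.53 ± 0.27. Cd9 did not pass (0.37, adjusted p = 0.157). It was -1.13 without the lipid-associated cluster (adjusted p = 0.00105), and 0.54 without MCD replicate 2, 0.61 with the GC trend removed and 0.71 with scaling by library totals, each of these past the threshold. The Kupffer cell genes Clec4f and Timd4 fell by 4.52 ± 0.70 and 4.60 ± 0.74, and Clec4f rested on 2 and 7 NCD cells and was not called without NCD replicate 2 (adjusted p = 0.0831). Mki67 was near the limit of detection (3.42 and 4.13 CPM, adjusted p = 0.755), and Ly6g had too few counts to be tested.

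In all, 4185 of 11112 tested genes passed, 2229 higher and 1956 lower. The split depends on the scaling, since without normalization factors 3842 genes were higher and 1106 lower. TMM put the median log2 fold change at 0.03 and library totals at 0.37, so the changes given are relative to the typical gene. The count was 2491 without NCD replicate 1, 2363 without NCD replicate 2 and 2103 with equal weight to each class. Fold changes also followed GC content, from a trend value of -0.32 at 33.8% GC to 0.63 at 54.4% GC of the transcript end, and 1688 genes were higher and 1801 lower with the trend removed. The trend had a Spearman correlation of 0.378 and a Pearson correlation of 0.301 across genes, which are not independent replicates.

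**Figure D1:**
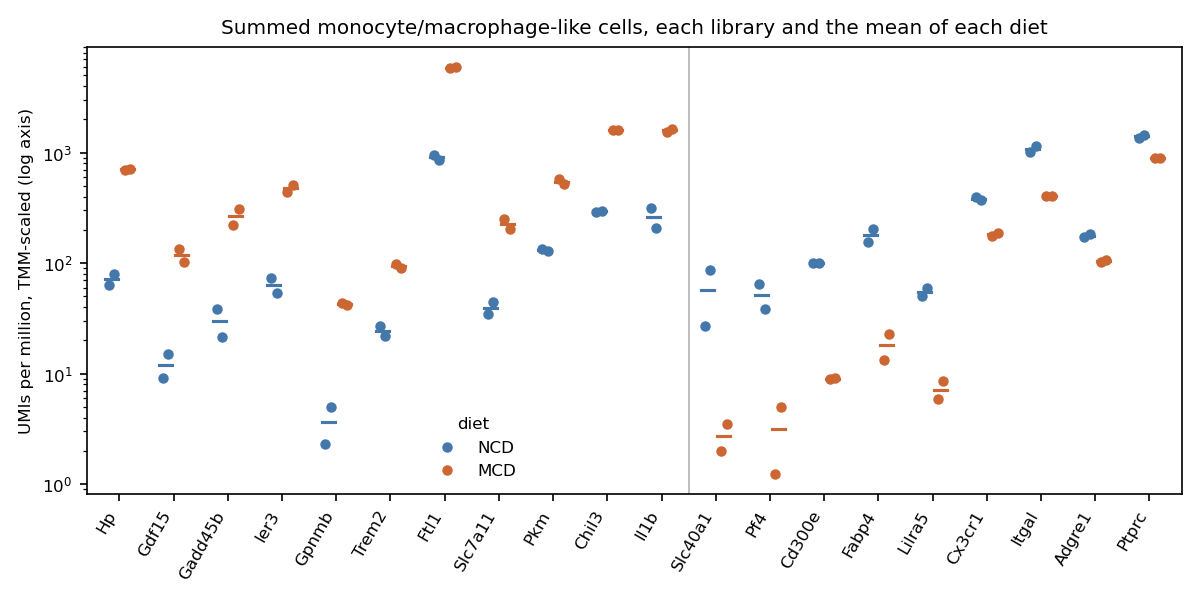
Summed UMIs as CPM (TMM-scaled, log axis) of 11 genes higher and 9 genes lower on MCD in monocyte and macrophage-like cells, with 1 point per library and a bar at the mean of each diet. Hp sits at 62.8 and 79.5 in the NCD libraries and at 695 and 716 in the MCD libraries, and Cd300e at 100.3 and 100.1 against 8.92 and 9.04.

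Genes of lipid-associated macrophages, glycolysis, the lysosome and the NRF2 antioxidant response rose together. Of 19 measured lipid-associated macrophage genes, 13 rose, 2 fell and 4 did not pass (13 and 2 adjusted over the list alone). The galectin Lgals3 rose by 1.61, the lysosomal protease Ctsd by 1.83, the fatty acid-binding Fabp5 by 2.21 and the lipid droplet gene Plin2 by 1.5 on the log2 scale, while Fabp4 and the fatty acid transporter Cd36 (-1.11) fell. The list was called by limma camera (adjusted p = 2.16e-09), with adjusted p = 0.23 with an estimated correlation. The union holds the lipid-associated macrophage-like cluster, with 501 and 415 MCD and 1 and 3 NCD cells. That cluster was named from markers shared with this list, so the call is partly fixed by the naming. Of 16 glycolysis genes 13 rose and 1 fell, the same counts as adjusted over the list alone, among them Pkm (2.04), Eno1 (2.06), Gapdh (1.36) and Gpi1 (1.44). The hexokinase Hk2, chosen after its value was seen, fell by 0.92. This list had an adjusted p of 1.11e-10 with camera and an adjusted p of 0.23 with an estimated correlation. Of 23 lysosome genes 15 rose and 1 fell (15 and 1 adjusted over the list alone), with Ctsz at 1.78 and Ctss at 0.58. The exception, Atp6v0c, named after its value was seen, fell by 0.76 and did not pass with scaling by library totals (adjusted p = 0.148 in edgeR), thinned counts (0.0566), equal weight to each class (0.134) or without NCD replicate 1 (0.263). Camera gave the lysosome list an adjusted p of 1.33e-05, and it was an adjusted p of 0.23 with an estimated correlation. Of 12 NRF2 targets 11 rose (11 adjusted over the list alone), and Gclc, at 0.54, did not pass (adjusted p = 0.144 in edgeR, but 0.0192 with scaling by library totals and 1.04e-04 without MCD replicate 2). Without the lipid-associated cluster Gclc was at -0.11. The ferritin light chain Ftl1 went from 907 ± 72.5 to 5894 ± 32.5 CPM, and the cystine transporter Slc7a11 rose by 2.52, the autophagy receptor Sqstm1 by 1.5 and haem oxygenase Hmox1 by 1.79. The NRF2 list had a camera adjusted p of 8.83e-11 and an adjusted p of 0.23 with an estimated correlation.

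Monocyte and Kupffer cell lists were also called. Of 13 Ly6Clo monocyte genes 9 fell and 1 rose, the same adjusted over the list alone. Cd300e, the integrin Itgal (-1.42), Cx3cr1 and the angiotensin-converting enzyme Ace (-1.49) fell, and the nuclear receptor Nr4a1 rose by 0.44 but did not pass without MCD replicate 2 (adjusted p = 0.0817 in edgeR) or with equal weight to each class (0.102). The camera adjusted p was 9.54e-10, with an adjusted p of 0.23 with an estimated correlation. Of 15 Ly6Chi monocyte genes 7 rose, 2 fell and 6 did not pass (7 and 4 adjusted over the list alone). Chil3, a chitinase-like protein, went from 294 ± 1.99 to 1591 ± 2.62 CPM, the proteoglycan Vcan rose by 1.45 and lysozyme Lyz2 by 1.04, while Plac8 fell by 1.28 and Ms4a4c, named after its value was seen, by 0.74, the last not passing without NCD replicate 1 (adjusted p = 0.0712 in edgeR) or 2 (0.0979). The camera adjusted p was 6.12e-04, and adjusted p = 0.344 with an estimated correlation. Without MCD replicate 2 that list was not called (adjusted p = 0.198). Of 14 Kupffer cell genes 9 fell and 2 rose (10 and 3 adjusted over the list alone), with Folr2 at -7.18, the complement receptor Vsig4 at -5.25 and Slc40a1 among the falls. The exceptions were the transcriptional regulator Id3 (1.45) and Spic (1.67), which was named after its value was seen and was 0.38 without the lipid-associated cluster (adjusted p = 0.374 in edgeR). Camera gave this list an adjusted p of 5.03e-04, and it had an adjusted p of 0.289 with an estimated correlation. Counts thinned to the smallest library ended the call (adjusted p = 0.179).

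Cytokine, matrix and immediate early genes were higher as groups. Of 18 inflammatory cytokine and chemokine genes 8 rose, 1 fell and 9 did not pass (10 and 2 adjusted over the list alone). Interleukin 1 beta (Il1b) went from 262 ± 78.1 to 1596 ± 68.8 CPM and the neutrophil attractant Cxcl2 rose by 2.19. Il18, named after its value was seen, fell by 0.57 but did not pass with DESeq2 (adjusted p = 0.0948), thinned counts (0.296), scaling by library totals (0.354) or without either NCD library (0.188 and 0.121). The list had a camera adjusted p of 1.15e-03, an adjusted p of 0.471 with an estimated correlation and an adjusted p of 0.128 without the lipid-associated cluster. Of 18 matrix and growth factor genes 9 rose and 1 fell (9 and 2 adjusted over the list alone), with Tgfb1 at 1.45, the angiogenic factor Vegfa at 1.87, Tgfbi at 1.57 and fibronectin (Fn1) at 0.68. Mmp13, named after its value was seen, fell by 4.96. This list had a camera adjusted p of 8.06e-04, an adjusted p of 0.239 with an estimated correlation and an adjusted p of 0.0764 without the lipid-associated cluster. Of 19 immediate early and heat shock genes 12 rose and 3 fell, the same adjusted over the list alone. The transcription factor Atf3 rose by 1.5, the chaperone Hspa8 by 1.16 and Junb by 0.85, and Fos (-0.63), Dusp1 (-0.71) and Zfp36 (-0.45) fell. Zfp36 was named after its value was seen and did not pass with scaling by library totals (adjusted p = 0.205 in edgeR). The camera adjusted p was 6.16e-05, with an adjusted p of 0.467 with an estimated correlation.

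Of the 10 called lists, fry did not call the Kupffer cell (adjusted p = 0.0917), Ly6Chi (0.0638), inflammatory (0.101) and immediate early (0.101) lists. The other 14 lists were not called by camera. Oxidative phosphorylation genes went both ways, 7 up and 9 down of 19 (adjusted p = 0.466), with the small subunits Cox7a2 (-1.18), Cox6c (-0.96) and Ndufa4 (-0.96) lower. Of 16 ATF4 amino acid response genes 8 rose and 1 fell (adjusted p = 0.071), with Atf4 at 0.96, Cebpb at 0.90 and Ddit4 at -1.45, and the list passed with fry (adjusted p = 0.0331) and without NCD replicate 2 (0.0395). Of 17 methionine and choline genes 6 rose and 3 fell (adjusted p = 0.917). Their median was 0.41 while camera put the list lower, and Amd1, which makes the aminopropyl donor for polyamines and has near-identical copies, fell by 2.57. Of 10 MHC class II genes 2 rose and 1 fell (adjusted p = 0.466). The invariant chain Cd74 rose by 1.02, a call that was lost with the GC trend removed (0.30, adjusted p = 0.201 in edgeR), and the list passed without NCD replicate 1 (adjusted p = 0.0021). Of 20 type I interferon genes 1 rose and 6 fell (adjusted p = 0.241), and the list passed without MCD replicate 2 (adjusted p = 0.00614). Of 15 complement and efferocytosis genes 5 rose and 8 fell (0.523), with C3 at 0.98 and the anaphylatoxin receptor C5ar1 at 1.41, which did not pass with equal weight to each class (0.06). Of 14 alternative activation genes 5 rose and 5 fell (0.402), with the interleukin 4 receptor Il4ra at 2.05 and Klf4 at -0.85. Chemokine receptor and adhesion genes had 1 rise and 7 falls of 16 (0.11), with Icam1 at 1.91 and Cxcr4 at -0.77, and passed without NCD replicate 1 (0.0211). Cell cycle genes had 5 falls and no rise among 17 (0.106, with 2 falls adjusted over the list alone and a fry adjusted p of 0.0328). Rises and falls were 4 and 3 of 15 for ER stress (0.956), with Hspa5 at 0.70 and Xbp1 at -0.72, and 5 and 4 of 18 for apoptosis (0.956). They were 3 and 4 of 12 for cholesterol efflux (0.992, with Abcg1 at -0.89), 2 and 1 of 19 for cholesterol synthesis (0.917) and 4 and 1 of 16 for fatty acid oxidation (0.239). Over these lists alone the counts differed for cholesterol efflux (5 and 4), alternative activation (6 and 5) and chemokine receptors (1 and 8).

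**Figure D2:**
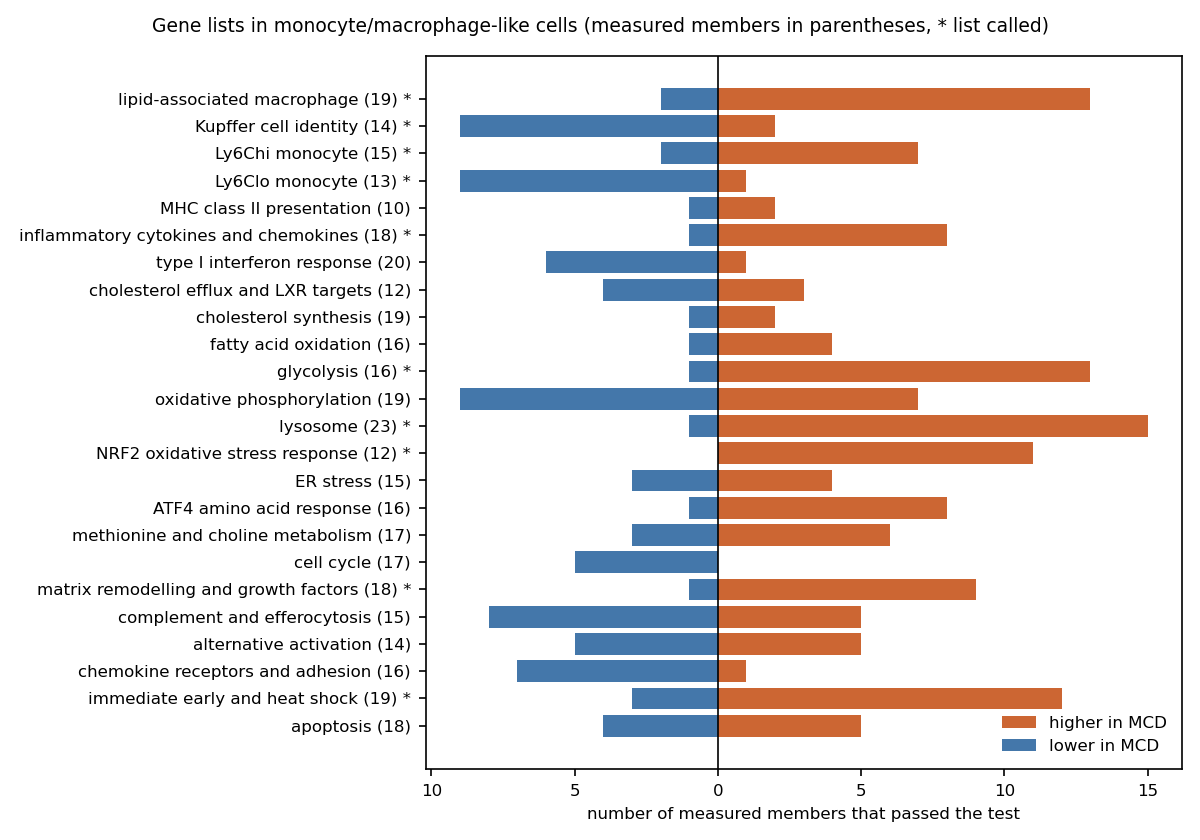
Number of measured members of each gene list that were higher (right) or lower (left) on MCD in monocyte and macrophage-like cells, with the measured total in parentheses and a star where limma camera called the list. The lysosome bar reaches 15 of 23 members and the glycolysis bar 13 of 16.

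Markers listed for other cell types also moved with diet in these sums. Endothelial genes were lower, 10 of 13 with none higher (camera adjusted p = 1.56e-06, and adjusted p = 0.587 with an estimated correlation), with Pecam1 at -2.78. In the NCD libraries Pecam1 was at 71.5 CPM in Ly6Clo-like and 9.43 in Ly6Chi-like monocytes, and Fabp4, also on this list, at 438 and 59.8. Their falls therefore need not stem from endothelial cells. Lower too were NK genes, 4 of 6 (0.0281, adjusted p = 0.517 with an estimated correlation), platelet genes, 3 of 3 (0.015, adjusted p = 0.587 with an estimated correlation), and pDC genes, 3 of 6 (0.0339, adjusted p = 0.517 with an estimated correlation). The calls of the NK and platelet lists were lost without NCD replicate 1 (0.161 each), that of the platelet list also without NCD replicate 2 (0.122), and that of the pDC list without any of the 4 libraries (0.0929 to 0.319). Kupffer cell markers were lower, 10 of 13 with 2 higher (3.72e-05), Ly6Clo markers lower, 10 of 14 with 1 higher (2.96e-11), lipid-associated macrophage markers higher, 9 of 13 with 1 lower (5.05e-09), and Ly6Chi markers higher, 5 of 13 with 2 lower (0.0104, lost without MCD replicate 2 at 0.334). These 4 had an adjusted p of 0.517 with an estimated correlation. The lipid-associated markers had also named a cluster of the union with almost only MCD cells, so their call is partly fixed by the naming. Neutrophil genes were not called, 2 higher and 5 lower of 11 (0.492), but they and the plasma cell list were lower without NCD replicate 2 (1.46e-10 each), and the erythroid list was higher without MCD replicate 1 (2.01e-05). Among them S100a8 fell by 5.69 ± 1.52 with 71.1% of its UMIs in NCD replicate 1 in 1 cell, and was at 0.91 without that library. S100a8 also did not pass at Leiden resolution 2.0 (adjusted p = 0.171 in edgeR) or with values scaled within each library (0.336). The macrophage (6 higher, 6 lower of 14), cDC1 (3 and 3 of 10), cDC2 (2 and 4 of 10), migratory DC (4 and 1 of 11), eosinophil (1 and 0 of 3), basophil (0 and 1 of 3), ILC2 (0 and 0 of 3), B cell (0 and 1 of 3), plasma cell (1 and 2 of 4), hepatocyte (1 and 1 of 6), cholangiocyte (1 and 0 of 4), erythroid (0 and 0 of 5) and peritoneal macrophage (2 and 3 of 7) lists were not called by camera, with camera adjusted p of 0.262 or more. Adjusted over a list alone, counts differed for Ly6Chi markers (4 lower), macrophage (7 lower), Kupffer cell (11 lower), neutrophil (6 lower), eosinophil (0 higher) and endothelial markers (11 lower). The T cell and stellate cell lists had 2 measured members each and were not tested.

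Within Ly6Chi-like monocytes, Hp rose from 102 ± 4.58 to 908 ± 37.7 CPM (SD, n = 2) and Trem1, an amplifier of myeloid inflammation, from 6.87 ± 3.65 to 83.1 ± 21.6 CPM. Fabp4 fell from 56.4 ± 8.89 to 4.13 ± 3.68 CPM. The adjusted p were 2.24e-07, 3.96e-05 and 2.21e-04 in edgeR. Glycolysis genes (12 rose, 1 fell of 16, camera adjusted p = 2.87e-07, adjusted p = 0.415 with an estimated correlation) and lysosome genes (12 rose, 2 fell of 23, 8.08e-04, adjusted p = 0.415 with an estimated correlation) were higher. MHC class II genes were lower, with 4 of 8 fallen and none risen (5.22e-05, adjusted p = 0.58 with an estimated correlation), and Ly6Clo monocyte genes were lower too, 6 of 13 with 1 higher (1.33e-04, adjusted p = 0.415 with an estimated correlation). In all 10 of the 24 gene lists were called in this class, and none with an estimated correlation (smallest adjusted p = 0.415). Endothelial markers fell here as well, 9 of 13 (2.89e-05, adjusted p = 0.588 with an estimated correlation). In this class 2880 of 9763 genes passed, 1464 higher and 1416 lower, and the split was 3579 and 659 with scaling by library totals, which moved the median from 0.04 to 0.53, and 1001 and 1348 with the GC trend removed. Without NCD replicate 1 the count was 1911 and without NCD replicate 2 it was 1641.

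Within Ly6Clo-like monocytes, Hp rose from 37.9 ± 8.32 to 353 ± 24.9 CPM and Ninj1, which encodes a membrane protein of cell lysis, from 13.5 ± 8.78 to 173 ± 10.4 CPM (SD, n = 2). Cd300e fell from 311 ± 14.5 to 34.8 ± 1.1 CPM, the RNA-binding protein gene Zfp36l1 from 1133 ± 66.0 to 165 ± 2.63 CPM and Pecam1 from 77.1 ± 2.43 to 7.86 ± 0.280 CPM. The adjusted p were between 1.58e-05 for Cd300e and 2.34e-04 for Ninj1 in edgeR. Ly6Clo monocyte genes were lower in the class that carries that name, 8 of 13 with none higher (camera adjusted p = 3.49e-11, adjusted p = 0.48 with an estimated correlation), and Ly6Chi genes were higher, 10 of 15 with 1 lower (1.77e-10, adjusted p = 0.201 with an estimated correlation). These sums do not separate a change within cells from a mixture of cells in the MCD class. Matrix genes (8 of 13 rose, none fell, 1.96e-07, adjusted p = 0.201 with an estimated correlation) and glycolysis genes (9 of 16 rose, none fell, 2.04e-06, adjusted p = 0.201 with an estimated correlation) were higher, and 10 of the 24 gene lists were called, none of them with an estimated correlation. Endothelial markers were lower here as well, 3 of 13 with none higher (2.07e-04, adjusted p = 0.613 with an estimated correlation). Of 9114 genes 1795 passed, 949 higher and 846 lower. The split was 1770 and 523 with scaling by library totals (median from 0.05 to 0.32) and 486 and 697 with the GC trend removed, and 1128 genes passed without NCD replicate 2.

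Within C1q-expressing macrophages, 4 genes named by rule had no UMI on MCD. Retnla was at least 941-fold lower, Vsig4 at least 166-fold lower, the B cell attractant Cxcl13 at least 114-fold lower and the folate receptor Folr2 at least 74.9-fold lower, each with no UMI in the 46 and 64 MCD cells and an adjusted p of 3.9e-06 or less in edgeR. The value of Retnla rests on few NCD cells, as given above for the union. These sums do not separate a change within cells from a change in which cells make up the class. Csf2rb2, a cytokine receptor subunit with no NCD UMI, was at least 5.82-fold higher (adjusted p = 7.00e-04 in edgeR). Kupffer cell genes, which had tied for the name of this class in NCD cells alone, were lower, 6 of 10 with 1 higher (camera adjusted p = 4.98e-07, adjusted p = 0.315 with an estimated correlation), and MHC class II genes were higher, 7 of 9 with none lower (1.66e-08, adjusted p = 0.315 with an estimated correlation). Peritoneal macrophage markers were lower, 3 of 4 with 1 higher (1.04e-04, adjusted p = 0.332 with an estimated correlation). Here 8 of the 24 gene lists were called, and none with an estimated correlation. Of 5193 genes 919 passed, 420 higher and 499 lower. The split was 707 and 320 with scaling by library totals (median from 0.04 to 0.26), 692 and 361 with no filter, 360 and 257 without MCD replicate 1 and 220 and 445 with the GC trend removed. The count was 259 without NCD replicate 1 and 484 without NCD replicate 2.

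In the other classes several of the same genes passed. In cDC2-like cells the chemokine Ccl22 rose from 5.01 ± 1.45 to 98.3 ± 5.89 CPM and Gadd45b from 22.0 ± 12.0 to 227 ± 29.8 CPM, and the leptin receptor Lepr (-2.78) and Amd1 (-2.61) fell. In endothelial cells Gdf15 rose by 3.14, Hp by 3.0 and the clock gene Nr1d1 by 3.66, while Cd300e (-3.87) and the NK protease gene Gzma (-3.34) fell, the last not passing with DESeq2 (adjusted p = 0.247). Cd300e and Gzma are genes of monocytes and NK cells, so their falls may come from RNA of other cells or doublets, which was not tested. Hp also rose in the monocyte classes. Its rises here and in eosinophil-like cells may have the same sources, which was not tested either. In eosinophil-like cells Hmox1 was at least 8.53-fold higher and Hp at least 4.50-fold higher on MCD, and the interferon-induced Gbp2 fell by 3.26. The call of Hp there was lost without NCD replicate 1 (adjusted p = 0.192 in edgeR) or MCD replicate 1 (0.0676). In NK-like cells Nfkb2, an NF-kappaB subunit, was at least 5.80-fold higher, a call that was lost without NCD replicate 2 or MCD replicate 2. The interferon-induced Ifi27l2a (-4.23) and H2-Aa (-3.77) fell there. NK-like cells should lack H2-Aa, so its fall may likewise come from RNA of other cells. In migratory DC-like cells the eosinophil attractant Ccl24 went from 348 ± 174 to 1.98 ± 1.59 CPM and the phosphatase Dusp6 fell by 4.20. The dynactin subunit Dctn2 was at least 4.96-fold higher, a call lost without NCD replicate 1. Ace and Fcgr4 were also among the 4 largest falls there. Both were top genes of the NCD Ly6Clo-like cluster, so their falls may come from RNA of other cells or doublets, which was not tested.

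The numbers of genes that passed were 2777 of 9165 in cDC2-like cells (1394 higher, 1383 lower), 2904 of 9557 in endothelial cells (1579, 1325), 534 of 5636 in migratory DC-like cells (299, 235), 446 of 2145 in NK-like cells (181, 265) and 203 of 5228 in eosinophil-like cells (131, 72). Scaling by library totals gave splits of 4032 and 517, 1930 and 947, 467 and 198, 568 and 124, and 118 and 58 in the same order, with medians of 0.67, 0.12, 0.42, 0.54 and 0.12. With the GC trend removed the splits were 870 and 1326 in cDC2-like cells, 811 and 926 in endothelial cells, 144 and 303 in migratory DC-like cells and 65 and 75 in eosinophil-like cells. DESeq2 gave 664 and 994 in cDC2-like, 126 and 182 in migratory DC-like and 59 and 142 in NK-like cells. With no filter on low counts the splits were 361 and 134 in migratory DC-like and 123 and 24 in eosinophil-like cells. Leaving out 1 library lowered the endothelial count to 1671 (without NCD replicate 2), the eosinophil count to 115 (91 and 24, without NCD replicate 1), 102 (82 and 20, without MCD replicate 1) and 85 (72 and 13, without MCD replicate 2), and the migratory DC count to between 163 and 354. Across the 8 classes, 171 genes were higher and 178 lower on MCD in at least 6, of 5236 tested in at least 6. Ribosomal protein genes made up 11 of those higher and 37 of those lower.

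The diet effect differed between Ly6Chi-like and Ly6Clo-like monocytes for H2-Aa and Cd74, 2 genes of antigen presentation, and no list was tested for this difference. H2-Aa, an MHC class II chain, went from 1178 to 179 CPM in Ly6Chi-like and from 1528 to 1850 CPM in Ly6Clo-like cells, a log2 difference of the diet effects of 2.98 ± 0.15 (SE, edgeR adjusted p = 4.47e-16). Cd74 went from 1405 to 652 CPM in Ly6Chi-like and from 1643 to 5094 CPM in Ly6Clo-like cells, a difference of 2.73 ± 0.13. The chemerin receptor Cmklr1 differed by 2.84 and Camp by 6.63, and Zfp36l1 (-2.09), Nbn (-2.63), the sodium channel subunit Scnn1a (-2.14) and Spata13 (-2.06) differed the other way. In all 516 of 9616 genes differed, 394 with a higher and 122 with a lower diet effect in Ly6Clo-like cells. The summed CPM of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in NK-like cells, which should lack them, was 3087 and 2519 in the NCD libraries, against 3061 and 2568 in NCD Ly6Chi-like cells, and it was 427 and 768 in the MCD libraries. With median depths of 1401 and 1212 UMIs in NCD and 6375 and 5428 in MCD NK-like cells, the NCD Ly6Chi level was 0.99 and 1.02 times that of cells that should lack these genes. H2-Aa differed by 1.33 at Leiden resolution 2.0 and by 1.88 with values scaled within each library. The calls were lost for Camp without NCD replicate 1 (0.60, adjusted p = 0.962) or MCD replicate 1, for Cmklr1 and Nbn without NCD replicate 2 (0.0891 and 0.113), for Cmklr1 also without NCD replicate 1 (0.18), and for Cmklr1 and Scnn1a with values scaled within each library (0.118 and 0.0554).

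**Figure D3:**
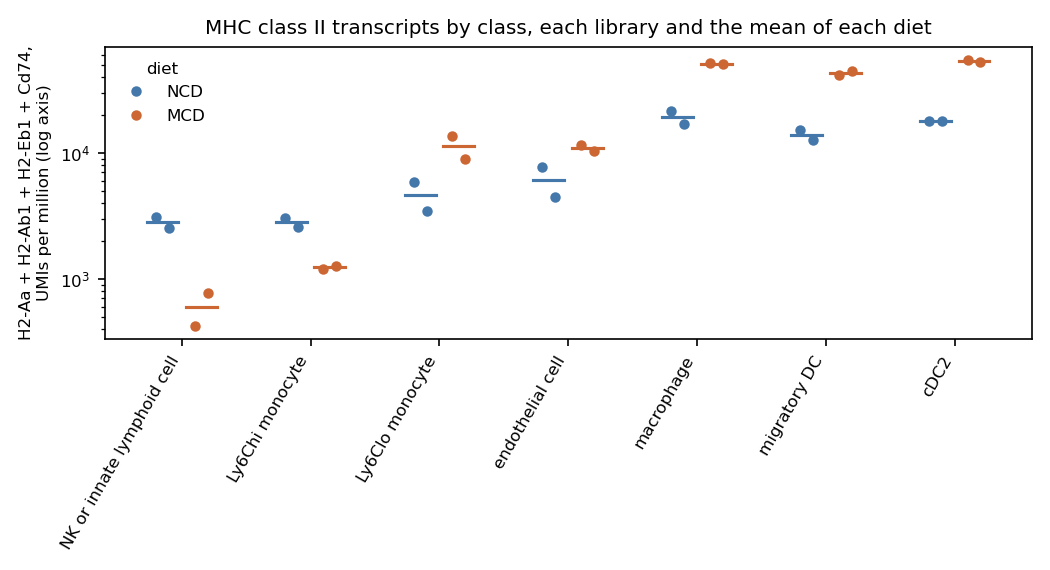
Summed CPM of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 (log axis) by class, with 1 point per library and a bar at the mean of each diet. The MCD libraries sit at 1205 and 1277 in Ly6Chi-like and at 13700 and 8966 in Ly6Clo-like monocytes.

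Over all retained cells, Gdf15 (log2 rise of 3.90), Hp (3.88), Lars2 (3.55) and Erdr1 (4.02) rose, and the liver fatty acid-binding protein gene Fabp1 (-5.39), S100a8 (-3.80), the collagen chaperone Serpinh1 (-3.80) and Retnla (-3.55) fell. Hp went from 37.4 ± 5.59 to 551 ± 14.5 CPM (SD, n = 2), and Fabp1 from 51.0 ± 23.0 to 1.20 ± 0.0642 CPM. The adjusted p in edgeR ran from 2.52e-04 for Hp and Lars2 to 7.49e-03 for S100a8. Of 12740 genes 6253 passed, 3328 higher and 2925 lower, with changes in the make-up of the cells included. Erdr1 did not pass without NCD replicate 1 (adjusted p = 0.0506), and scaling by library totals moved the median from 0.02 to 0.13.

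Lipid-associated macrophage-like cells made up 0.113% ± 0.0781 (SD, n = 2) of NCD and 15.1% ± 2.66 of MCD cells, a difference of 15 points that was 7.35 at Leiden resolution 2.0, where the MCD cluster of that name also had C1q genes in its top 10. At that resolution an unnamed cluster of 314 NCD cells had Ccl24, Il1rn and Lpl in its top 10, which the MCD cells of the lipid-associated cluster had as well. The near absence of the class in NCD may therefore rest in part on the naming rule. With values scaled within each library 517 MCD cells shared a cluster with 134 NCD cells that alone would be named macrophage, so the class is not compared there. Eosinophil-like cells made up 4.47% ± 3.07 of NCD and 21.2% ± 7.28 of MCD cells, endothelial cells 16.9% ± 6.21 and 5.53% ± 2.78, and NK-like cells 3.82% ± 1.73 and 0.890% ± 0.132. The deposited barcodes began at 500 to 502 UMIs. Median eosinophil-like cells lay near that floor, at 767 and 757 UMIs in NCD and 1336 and 1241 in MCD. More of them may be missing from the shallower NCD libraries, so their difference in share cannot be told apart from depth. The 4 monocyte and macrophage classes together made up 37.7% ± 0.835 of NCD and 53.6% ± 0.968 of MCD cells, cDC2-like cells 18.3% ± 3.27 and 10.8% ± 2.64, and macrophages 3.39% ± 0.834 and 1.80% ± 0.339. The difference for the cDC2 class, -7.50 points, became 8.94 with values scaled within each library, where a cluster of 610 NCD cells with cDC2 markers was left unnamed because its MCD cells got another name. Without NCD replicate 2 the difference was -7.00 for the endothelial cell class (-11.4 with all libraries) and -1.71 for the NK or innate lymphoid cell class (-2.93). With up to 20% mitochondrial UMIs the endothelial value was -17.3, and with at least 500 genes the NK value was -1.65. For the macrophage class it was -1.002 without NCD replicate 1 (-1.59). Ly6Chi-like shares overlapped (24.4% ± 0.988 and 24.7% ± 4.0). The Ly6Clo monocyte class made up 9.83% ± 0.603 and 12.0% ± 0.712, but the difference of 2.15 points became -2.48 points at Leiden resolution 2.0 and -0.146 with values scaled within each library. At resolution 0.5 (-9.30) no cluster of MCD cells had the Ly6Clo name. The difference for the union, monocyte/macrophage (4 classes), 15.9 points, was 6.08, 3.85 and 3.32 in the clusterings at resolution 0.5 and 2.0 and with values scaled within each library. Migratory DC-like cells (1.71% and 2.99%), neutrophil-like cells (2.81% and 0.753%), basophil-like cells (2.97% and 0.147%) and the unnamed clusters (11% and 2.28%) also had both MCD libraries on 1 side of both NCD libraries. The difference of the unnamed clusters, -8.76 points, was 1.14 at resolution 0.5 and 4.53 at 2.0, that of the migratory DC class, 1.28, was 0.743 without NCD replicate 2 and 0.830 without MCD replicate 2, and that of the basophil or mast cell class, -2.82, was -1.82 without NCD replicate 2 and -1.28 with at least 500 genes. With 2 libraries per diet no exact permutation p can fall under 0.33, and the mitochondrial filter had removed a larger part of the NCD barcodes.

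**Figure D4:**
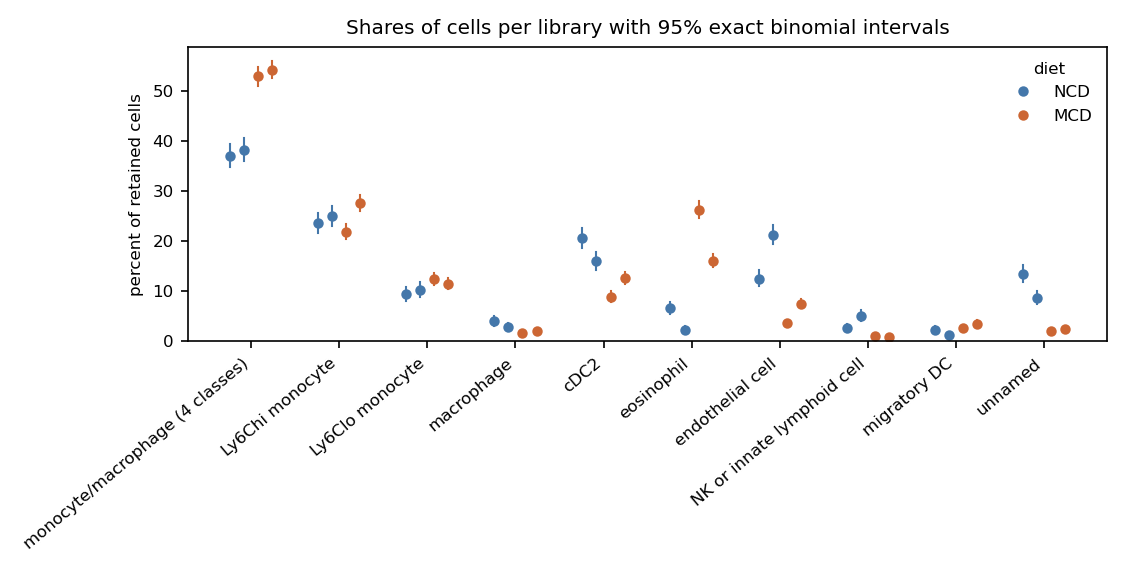
Percent of retained cells in each class, with 1 point per library and exact binomial 95% intervals, which cover counting error only. Eosinophil-like cells reach 26.3% and 16% in the MCD libraries against 6.64% and 2.30% in the NCD libraries. Their NCD medians of 767 and 757 UMIs lie near the smallest deposited barcodes of 502 UMIs, so this difference depends on depth.

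At an equal 1000 UMIs per cell, Trem2 was seen in 2.21% ± 0.210 of NCD and 8.79% ± 1.11 of MCD monocyte and macrophage-like cells (SD, n = 2), and Gpnmb in 0.378% ± 0.09 and 2.5% ± 0.284. Median depths before thinning were 1986 and 2004 UMIs in NCD and 13829 and 13052 in MCD cells. In cDC2-like cells, with medians of 2493 and 2520 in NCD and 16507 and 15402 in MCD, Trem2 was seen in 0.140% and 0.252% of cells. It was seen in 0.639% and 2.92% of endothelial cells and in 1.32% of NCD NK-like cells, 1 of 38 and 0 of 62. Gpnmb was seen in 0 of 356 and 0 of 283 NCD and 0 of 263 and 0 of 397 MCD cDC2-like cells, which allows shares with a UMI of up to 0.843%, 1.06%, 1.14% and 0.756%. NK-like cells were too few to bound the background more closely, with no Trem2 or Gpnmb UMI in 29 and 24 MCD cells, which allows up to 10.3% and 12.5%. Spp1 was seen in 0.305% ± 0.0140 and 2.07% ± 0.431 of the union, in 0 of 29 and 1 of 24 MCD NK-like cells, and in 0.368% of Ly6Chi-like, 0.552% of Ly6Clo-like, 1.01% of cDC2-like and 5.84% of lipid-associated macrophage-like cells on MCD. Cd9 was seen in 6.81% and 8.77% of the union, 12.5% and 18.7% of NK-like and 0.953% and 1.76% of Ly6Chi-like cells, so NK-like cells set no floor for it. Mki67 was near the limit of detection (0.231% and 0.428%, against 2.93% and 1.72% of NK-like cells). Cx3cr1 was seen in 26.1% ± 3.21 and 18.6% ± 0.806 of cells, against 17.0% and 5.53% of NK-like cells, some of which express it, and Adgre1 in 14.4% ± 1.92 and 10.4% ± 0.467. Itgam was seen in 22.2% and 25.1% against 19.99% and 22.5% of NK-like cells, Ccr2 in 40.4% and 43.5% against 13.5% and 22.8%, Ly6c2 in 23.9% and 30.02% against 18.9% and 30.1% (and 4.05% and 4.61% of cDC2-like cells), and H2-Ab1 in 28.5% and 32.0% against 22.8% and 19.4%. The libraries of the 2 diets overlapped for Cd9, Ccr2, Ly6c2 and H2-Ab1. Clec4f (0.526% and 0.12%) and albumin (0.310% and 0.746%) were near the limit of detection. Timd4 was seen in 0.305% ± 0.0140 of NCD cells and in 0 of 1557 and 0 of 1699 MCD cells, which allows up to 0.193% and 0.177%, and in 1 of 62 cells of the NK-like class in NCD replicate 2. Not thinned, Trem2 was seen in 4.53% and 53.6% of cells.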

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

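The test of the difference between classes was planned. The predictions for the tests on single cells and on the border between the classes concern a pattern already seen, and were written before these tests. The clusterings at resolution 2.0 and on scaled values entered the class by diet term after the data were seen. The 2 tests of free RNA were chosen after the result was seen. The diet effect of 516 genes differed between Ly6Clo-like and Ly6Chi-like monocytes by the class by diet term in edgeR. Among the genes named by rule the difference was positive (a higher diet effect in Ly6Clo-like cells) for the class II genes H2-Aa (2.98) and Cd74 (2.73), for Cmklr1 (2.84) and Camp (6.63), for the lipid-sensing receptor gene Trem2 (1.80), and for the classical monocyte genes Ccr2 (0.97) and Ly6c2 (0.86). It was negative for Zfp36l1 (-2.09), Nbn (-2.63), Scnn1a (-2.14), Spata13 (-2.06), the F4/80 gene Adgre1 (-0.79) and the tetraspanin gene Cd9 (-1.04). The value of Cmklr1 rests on 3 UMIs in NCD Ly6Clo-like cells, and that of Camp on a few NCD cells.

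The pattern weighed here concerns the summed CPM of H2-Aa, H2-Ab1, H2-Eb1 and Cd74, not the whole MHC class II list. This sum was lower on MCD in Ly6Chi-like monocytes. In Ly6Clo-like monocytes it was 5875 and 3457 in the NCD and 13700 and 8966 in the MCD libraries. A few cells with very high counts as the only source are argued against, since at 1000 UMIs per cell the lowest median of the MCD Ly6Clo-like cells was 2 class II UMIs and the highest NCD median was 1. A larger subset of high cells stays open, since a median cannot show how much of the sum such cells hold. The upper quartiles were 19.5 and 9 UMIs in MCD and 5 and 2 in NCD. At Leiden resolution 2.0 an unnamed cluster of 321 MCD cells had Cd74 and Ciita in its top 10. Free RNA from dendritic cells is argued against for the MCD Ly6Clo-like level, which was at least 11.7 times that of NK-like cells in the same library. For the NCD Ly6Chi-like level free RNA stays open as a candidate source. That level was at most 1.02 times and at least 0.99 times the NK-like level. These levels are shares of UMIs, and Ly6Chi-like cells had medians of 1983.5 and 2004 UMIs in NCD and 13556 and 12865 in MCD. The fall in Ly6Chi-like cells may therefore be a fall in the share of free RNA, which deeper cells can show without less free RNA per cell. NCD NK-like cells had medians of 1401 and 1212 UMIs, so equal CPM need not mean equal free RNA per cell. The border between the classes also stays open. The H2-Aa difference was 1.33 ± 0.11 (SE) at Leiden resolution 2.0 and 1.88 ± 0.12 with values scaled within each library, both above the bound of 1. Resolution 0.5 left no Ly6Clo-like MCD cluster and gave no value. A change of the monocytes with diet, the biological explanation the design names, was therefore not separated from these sources.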

How the results depend on the processing

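Scaling by library totals, the GC correction, the removal of high doublet scores, the unnamed clusters, the clustering on scaled values and the union without its lipid-associated cluster were chosen after the data were seen. Of 2522 alternative values for 147 gene results, 2435 kept the direction and the side of the threshold, 54 no longer passed, 12 newly passed and 21 changed sign. For 46 list results 428 of 483 values kept their call, 44 lost it and 11 gained it, and with an estimated correlation 0 gene lists were called in the union (10 with the preset value). Leaving out 1 library leaves a diet with a lone library, which is assumed to vary like the others, and gives fewer samples. Depth limits the NCD libraries: with 2 libraries per diet the test recovered 52% of simulated 2-fold changes in the union and 37% in Ly6Clo-like monocytes and macrophages. No cluster was named Kupffer cell-like, so the planned union with such clusters was not run, and the class by diet term gave no value at Leiden resolution 0.5. Except where samples or counts were fewer, the cause was not tested.

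Leaving out each library in turn gave 2363 to 3848 changed genes in the union, 1641 to 2529 in Ly6Chi-like, 1128 to 2040 in Ly6Clo-like, 1671 to 2753 in endothelial, 85 to 172 in eosinophil-like, 259 to 621 in macrophage and 163 to 354 in migratory DC-like cells. Equal weight to each class gave 2103 in the union. DESeq2 gave 201 in NK-like, 1658 in cDC2-like, 1242 in endothelial, 60 in eosinophil-like, 370 in macrophage and 308 in migratory DC-like cells. Thinned counts gave 284 in NK-like, 22 in eosinophil-like, 555 in macrophage and 251 in migratory DC-like cells. Scaling by library totals gave 692 in NK-like and 4549 in cDC2-like cells, and the GC correction 1183 in Ly6Clo-like and 1737 in endothelial cells. With a replicate block, which the labels do not establish, 4173 genes passed in the union.

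The difference in share (MCD minus NCD, in points) for the Ly6Clo monocyte class was -9.30 at Leiden resolution 0.5 (where no MCD cluster had that name), -2.48 at 2.0, -0.146 with values scaled within each library and 3.13 with up to 20% mitochondrial UMIs. For the macrophage class it was -3.07 and -3.10 at resolutions 0.5 and 2.0, where MCD cells with C1q genes lay in clusters named lipid-associated and no MCD cluster was named macrophage. For the union, monocyte/macrophage (4 classes), it was 6.08 and 3.85 at these, 3.32 with scaled values and 14.01 with at least 500 genes. The difference in cells with a UMI was 13.4 points thinned to 2000 UMIs and 49.1 not thinned for Trem2, 3.83 and 11.6 for Gpnmb, and 2.43 and 8.12 for Spp1, which follows from more UMIs per cell.

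In the union the log2 value changed sign for Ccr2 (0.10 with library totals, 0.064 with equal weight), Cd9 (-1.13 without the lipid-associated cluster, -0.51 with equal weight), Gclc (-0.11 and -0.25 in these), and Itgam (0.11 with library totals, 0.043 with the GC correction). It did so for Ly6c2 (0.32 with library totals, 0.084 with no filter, 0.066 at Leiden resolution 2.0, 0.17 without the lipid-associated cluster, 0.051 with equal weight, and -0.51 to 0.30 with 1 library left out). Mki67 was at -0.10 at resolution 0.5, -0.081 with values scaled within each library, -0.093 with the unnamed clusters, -0.49 without the lipid-associated cluster and -0.53 to 2.55 with 1 library left out, and S100a8 at -6.65 to 0.91 with 1 library left out.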

Other observations

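The predictions for GC content and transcript length concern a pattern already seen, and were written before these tests. The tests of the GC trend as the only cause, free RNA, shared barcodes, library totals and the lipid-associated cluster were chosen after the results were seen. Within the Ly6Clo-like class, at 1000 UMIs per cell, Ccr2 was seen in 14.4% ± 3.14 of NCD and 37.1% ± 1.11 of MCD cells (SD, n = 2) and Ly6c2 in 4.69% ± 0.349 and 14.8% ± 3.97, while the share with Cd9 was 19.7% ± 3.54 and 8.15% ± 1.12. Trem2 was seen in 1.79% ± 0.96 and 10.6% ± 1.57 of these cells and in 4.79% ± 3.94 and 19.3% ± 7.34 of C1q-expressing macrophages. Ly6c2 was seen in 18.9% and 30.1% of NK-like, 4.05% and 4.61% of cDC2-like and 2.85% of MCD eosinophil-like cells, so NK-like cells set no floor for it, and the NCD share in Ly6Clo-like cells was near that of cDC2-like cells. At Leiden resolution 2.0 an unnamed cluster of 321 MCD cells had Ccr2, Cd74 and Ciita in its top 10. Whether the MCD Ly6Clo-like class held such cells was not tested, so a mixture of cells and a change of state cannot be told apart here.

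Several genes changed alike across cell types. The chaperone gene Hspa8 (median log2 fold change 1.11) and Atf3 (1.73) rose in all 8 tested classes, as did Ftl1 (2.49), and Fabp4 (-2.91) and Dusp1 (-0.78) fell in all 8. In all, 19 genes rose and 3 fell in all 8 classes, of 1911 tested in all. Amd1 (median -2.41) fell in 7 classes and Pkm (1.88), Eno1 (1.91) and Gadd45b (2.55) rose in 7. Called in opposite directions in 2 classes were 94 genes. Summed class II CPM was higher in both MCD libraries in cDC2-like cells (17936 and 17972 in NCD, 54266 and 52282 in MCD), macrophages (21645 and 17074, 51902 and 50327) and migratory DC-like cells (15172 and 12552, 41125 and 44584). The same held for Ly6Clo-like (5875 and 3457, 13700 and 8966), endothelial (7685 and 4467, 11572 and 10338.5) and eosinophil-like cells (2400 and 189, 3171 and 3291.5). It was lower in both MCD libraries in NK-like (3087 and 2519, 427 and 768) and Ly6Chi-like cells (3061 and 2568, 1205 and 1277).

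The first pattern weighed is the 171 genes higher and 178 lower in at least 6 of the 8 classes. A GC trend as the only cause is argued against, because 194 of the 349 genes (62 higher and 132 lower) still passed in at least 6 classes with the trend removed. GC bias as a part of the cause stays open: the higher genes had a median GC content 10.0 points above the lower genes (51.0% against 41.0%, bootstrap interval 7.5 to 12.1). Free RNA stays open too: 18.7% of 337 genes (95% interval 14.7 to 23.3) changed at least as much in eosinophil-like cells, which hold the fewest UMIs, as in Ly6Chi-like monocytes, an interval that includes the bound of 20%, and Fabp4 fell in all 8 classes. The length ratio of 1.25 (1.04 to 1.70) does not decide, and preparation cannot be told apart from diet. The 30 barcodes shared across diets (14 within) only argue against different barcode sets, so a stress response of all liver cells to the diet may contribute but is untested.

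The second is the breadth of the changes in the monocyte and macrophage union. A difference in library totals is argued against as its main cause. With all libraries thinned to the smallest, 3288 of 7874 tested genes passed, 3018 of them among the 4185. That thinning acted on summed counts and cannot address depth per cell. Median depths were 1986 and 2004 UMIs in NCD and 13829 and 13052 in MCD cells of the union, and an effect of depth per cell stays open. The lipid-associated cluster, present almost only on MCD in the clustering used, is argued against as the main cause as well, since 4009 genes passed without it, 3673 of them among the 4185. The make-up of the union by its other classes stays open as a part of the cause. With equal weight to each class 2103 of 7952 tested genes passed, 1973 of them among the 4185, but that setting also lowered the counts. An effect of the diet and a difference in preparation, each of which could produce this, cannot be told apart.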
